A study of Mus musculus with 9 samples.

How the data were processed

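Liver RNA of wild-type C57 BL6 mice, 8 weeks old and about 20 g in weight, was profiled for circular RNAs (circRNAs). The 9 libraries fall into 3 groups of 3 per the labels: saline controls, mice given 500 mg/kg acetaminophen (APAP), and mice given 300 µg/kg dmPGE2 1 hour before the same dose of APAP. Livers were taken 6 hours after APAP. Per the labels' protocols, libraries were made from 1 µg of total RNA depleted of ribosomal RNA, with strand marked by dUTP. No digestion of linear RNA is named there. The labels do not number the animals, so p-values measure the spread between these samples.

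The deposited table holds, per the file headers, 1 line per circRNA with its position, strand, host gene, overlapped features and, for each library, a count of back-splice junction reads and a TPM value. The counts are whole numbers that the authors left unscaled. The smallest count above 0 was 2 in every library, so a 0 need not mean that no read was seen. The deposited TPM is the count scaled by 1 constant per library, set by a value close to that library's circRNA total, so it carries no length term. TPM was used only to check the scaling, and CPM below was computed from the counts. The table also lists, per circRNA, reads at the same sites that do not cross the back-splice junction (non-junction reads), for libraries with back-splice reads only. In 1753 circRNAs (15.5%) this list had been turned into a single number and could not be split, so 9559 circRNAs had a usable list. The matching lists of junction reads gave 37463 items that could be compared with the count columns, and 0 differed. HISAT2 and the genome build GRCm38 (mm10) are named per the submitters' processing notes, without a role. The circRNA caller, its filters and software versions are not given in the sources used here.

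Count columns were matched to samples by name. The columns for APAP and for dmPGE2 with APAP carry the group and replicate number of the sample titles. The remaining 3 columns carry the code BC, which no label explains, and were assigned to the saline controls by elimination, with their own numbers 1 to 3. Deposited starts count from 0 and were raised by 1, after which 94.8% of 10591 exonic circRNAs had both ends at exon ends of the GENCODE M21 annotation of the same build. CircRNAs are named by their deposited identifiers. Host genes are those of the table. Of 251 circRNAs without a gene name, 119 took a symbol from their gene ID, and 126 circRNAs with more than 1 gene were kept as joint hosts. Of 10932 circRNAs with 1 gene ID found in the reference, 10888 (99.6%) had the same symbol there. CircRNAs were classed as exonic, intronic or intergenic by the features the table gives.

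Choices of groups, tests, gene lists, named genes and most alternatives were made before the data were examined. CircRNAs with at least 5 reads in at least 3 of the 9 libraries (4331) entered edgeR 4.0.16 in R 4.3.3. The quasi-likelihood F test was used with TMM scaling, 1 mean per group and all 9 libraries in the fit, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 3 comparisons were APAP with control, dmPGE2+APAP with APAP and dmPGE2+APAP with control, and a joint test asked whether any of the 3 groups differed. The same test was run on back-splice reads summed per host gene (2358 host genes past the same filter). Fold changes and their standard errors (SE) are from edgeR. CPM is back-splice reads per 1000000 reads of the library's circRNA total, given as mean ± SD. No fold is given against a group whose libraries are all listed at 0, except inside ranges over libraries left out, where such a fitted value depends on the prior count and is no bound.

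Host gene lists fixed beforehand covered drug metabolism, secreted plasma proteins, lipid and bile acid metabolism, amino acid and carbohydrate metabolism, pericentral and periportal hepatocytes, NRF2 and glutathione, stress response, inflammation and acute phase, prostaglandin signalling, Kupffer cells and macrophages, neutrophils and lymphocytes, sinusoidal endothelial cells, stellate cells and fibroblasts, cholangiocytes, widely reported circRNA hosts, splicing and circRNA handling factors, and proliferation. Of these 18 lists, 14 had at least 5 tested host genes and were tested with camera of limma 3.58.1 on log2 CPM of the host gene sums (prior count 2, preset correlation 0.01), adjusted over the lists. CircRNAs were named by a rule. It takes those past the threshold whose CPM ranges do not overlap between the groups, up to 10 rises and 10 falls. Where fewer than 10 passed, it takes those with the smallest unadjusted p up to 10 in all, given as not passing, and further the 8 with the highest mean CPM. For each list it takes up to 4 tested host genes with the highest mean CPM and any past the threshold up to 6. Some host genes that the rule takes from the lists are not reported here.

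Library totals, circRNAs detected after thinning to the smallest library, and the percent of reads per class were compared by exact permutation tests, 2-sided for pairs of groups, where 3 against 3 libraries cannot go below p = 0.1. Correlations of fold changes and, chosen after seeing the data, overlaps of calls between comparisons that share libraries were set beside 30 simulations with no effect. The circular share is 2 back-splice reads over the sum of 2 back-splice reads and the non-junction reads, since a linear RNA gives reads at both sites. Intervals on shares of single libraries are 95% Wilson intervals and cover counting error only. Alternatives included DESeq2 1.42.0 and limma-voom, other scalings and filters, the replicate number as a block, the groups of a pair alone, and each library left out in turn. Fits limited to circRNAs or host genes with reads in all 8 libraries other than control 3, and fits that also leave that library out, were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for library measures and plots.

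The tests were tested on simulated data with the libraries' own means and totals, 200 changed features per simulation and 5 simulations. For APAP with control, 1.49%, 16.1% and 36.1% of circRNAs changed 2-fold, 4-fold and 8-fold were recovered among 4331, with 8.25% false calls. For dmPGE2+APAP with APAP these were 3.58%, 18.2% and 36.4% with 10.7% false calls, and for dmPGE2+APAP with control 1.49%, 15.5% and 38.2% with 12.0% false calls. Over 2358 host genes, 4.78%, 34.3% and 51.8% were recovered for APAP with control, 8.96%, 35.5% and 52.4% for dmPGE2+APAP with APAP, and 9.25%, 37.6% and 48.8% for dmPGE2+APAP with control. Their false calls were 5.62%, 6.12% and 5.92%.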

Results

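CircRNAs, closed RNA rings made by back-splicing, were counted in mouse liver 6 hours after saline, after an acetaminophen overdose (APAP), and after the same overdose preceded by dmPGE2, a stable analogue of prostaglandin E2, with 3 libraries per group. The table held 11312 circRNAs of 3929 host genes or gene groups: 10591 exonic, 589 intronic and 132 intergenic. The 8 most abundant circRNAs came from Rnf169 (mmu_circ_0001605, mean 21320 CPM), Aass (novel_circ_0012103, 13210 CPM), Gigyf2 (mmu_circ_0000057, 12350 CPM), Ttc39c (novel_circ_0005475, 8642 CPM), Rmdn2 (novel_circ_0005331, 8502 CPM), Nfix (mmu_circ_0001704, 8226 CPM), an intergenic site on chromosome 4 (novel_circ_0010359, 7646 CPM) and Tmem56 (novel_circ_0009041, 7599 CPM). None of the 8 passed the edgeR test in any comparison with all 9 libraries (adjusted p 0.333 to 1). Aass encodes an enzyme of lysine breakdown and Nfix a transcription factor.

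Back-splice reads per library were 154449, 129971 and 4362 in control 1 to 3, 108667, 109453 and 69268 in the APAP group, and 120531, 99102 and 114791 in the dmPGE2+APAP group. Control 3 thus lay 25.7-fold below the median of the other 8 libraries and held reads of 739 circRNAs, against 3181 to 5214 in the others. At 391 circRNAs with usable values in all 9 libraries, reads of the circular form made up 6.14% in control 3 (95% Wilson interval 5.90% to 6.38%) and 66.1% to 75.7% in the others. This library stayed in the comparisons, as fixed beforehand, and values without it are given where it changes a result. No difference in totals by group passed with all libraries (exact permutation p = 0.979 over 1680 arrangements). Without control 3, both control libraries lay above every other library, with mean log2 totals of 17.11 in control, 16.52 in APAP and 16.76 in dmPGE2+APAP (exact permutation p = 0.0964 over the 3 groups, and 0.1 for control against each, the smallest that 2 against 3 allow). CircRNAs detected after thinning numbered 1461 ± 627 in control, 1805 ± 124 in APAP and 1865 ± 38.4 in dmPGE2+APAP (SD, n = 3, exact permutation p = 0.375), and 1822 ± 56.0 in control without control 3 (SD, n = 2, exact permutation p = 0.75).

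**Figure D1:**
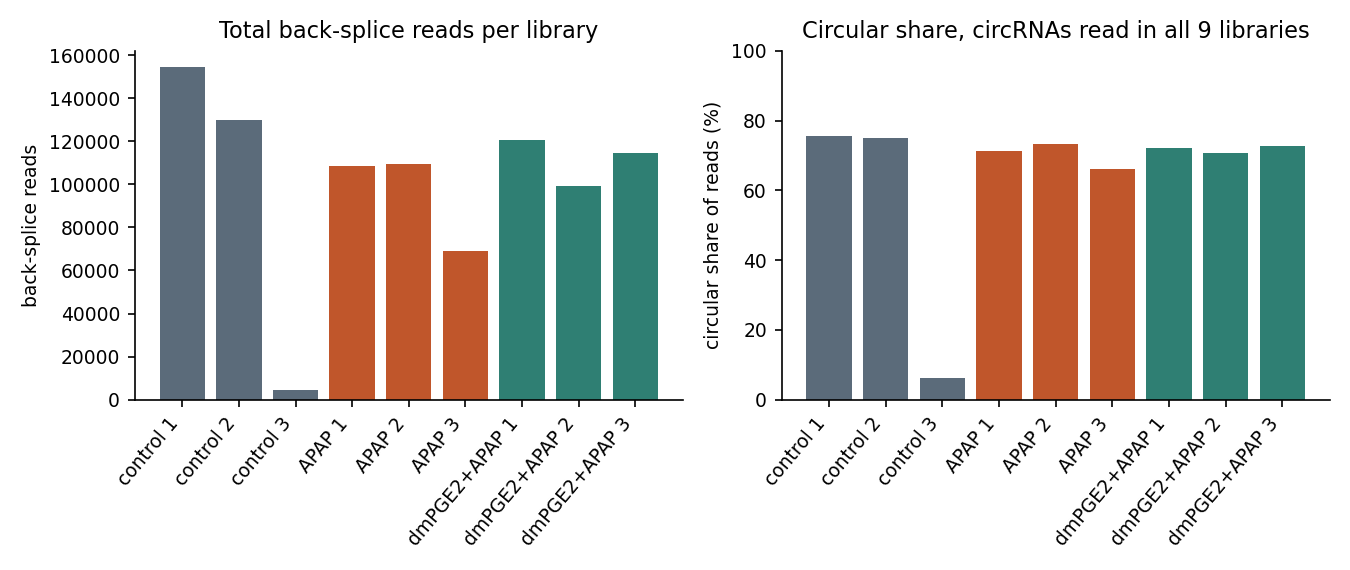
Back-splice reads per library (left, total reads) and the share of circular reads at 391 circRNAs measured in all libraries (right, percent), 1 bar per library coloured by group. Control 3 stands at 4362 reads and 6.14%, and the other 8 libraries lie between 69268 and 154449 reads and between 66.1% and 75.7%.

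Exonic circRNAs held 92.3% ± 3.21 of back-splice reads in control, 95.4% ± 0.387 in APAP and 95.4% ± 0.344 in dmPGE2+APAP (SD, n = 3, exact permutation p = 0.0321 over the 3 groups). Single control libraries stood at 93.6%, 94.8% and 88.7%, all below every APAP and dmPGE2+APAP library (95.1% to 95.9%). Against control, each treated group gave an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Leaving out 1 APAP or dmPGE2+APAP library at a time gave p between 0.0679 and 0.0857. On the percent of circRNAs in place of the percent of reads, the exonic difference over the 3 groups did not pass. Intergenic circRNAs held 4.25% ± 3.25, 1.33% ± 0.533 and 1.31% ± 0.505 (SD, n = 3, exact permutation p = 0.0571, and 0.0357 without control 2). Without control 3 the intergenic share in control was 2.41% ± 0.887 (SD, n = 2, exact permutation p = 0.154 over the 3 groups). In control 1, novel_circ_0010359 alone held 2.31% of back-splice reads, where all intergenic circRNAs held 3.04%. It was listed at 0 in APAP 3 and dmPGE2+APAP 1, where the intergenic share was 0.72% and 0.75%, and in control 3, where it was 7.93%. It had 1240 reads in control 2, 1163 and 971 in APAP 1 and 2, and 918 and 845 in dmPGE2+APAP 2 and 3. The intergenic shares of those libraries were 1.79%, 1.71%, 1.57%, 1.74% and 1.43%, in that order. Outside control 3 the class shares may thus rest largely on this circRNA, and shares without it were not computed. Intronic circRNAs held 3.40%, 3.22% and 3.27% (exact permutation p = 0.304).

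The comparison of APAP with control asked which circRNAs differ in liver 6 hours into APAP injury. Back-splice reads of Neat1, the long noncoding RNA that scaffolds nuclear paraspeckles, rose when summed over its circRNAs. They numbered 0, 3 and 0 in the control libraries and 88, 97 and 65 in the APAP libraries, a mean of 7.69 ± 13.3 CPM against 878 ± 64.7 CPM (SD, n = 3). Rings from Epha2, an ephrin receptor tyrosine kinase, rose 7.56-fold, and those from Trpc6, a calcium-permeable cation channel, rose 17.6-fold. Summed over host genes, Arhgap10, a GTPase-activating protein, rose 3.18-fold and Rmdn2, a microtubule-associated protein, fell 1.76-fold.

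By edgeR, 6 of 4331 circRNAs passed, 4 up and 2 down (12 without TMM scaling, 6 up and 6 down). The count was 10 without control 3 and 3 without APAP 1. The count at an unadjusted p under 0.05 was 219, where chance alone gives 216.6. It was 227 by DESeq2, 361 by limma-voom and 201 by edgeR without control 3. Among 1487 circRNAs with reads in all 8 other libraries, with control 3 left out, it was 146 (74.4 by chance). In that fit it was 77 in dmPGE2+APAP with APAP and 105 in dmPGE2+APAP with control. Of the Neat1 circRNAs, novel_circ_0006472 (19:5827505-5828042, minus strand) passed alone, listed at 0 in the 3 control libraries and at 36, 53 and 39 reads in the APAP libraries (460 ± 118 CPM, SD, n = 3, adjusted p = 1.03e-05). The Epha2 circRNA mmu_circ_0001290 (4:141306514-141309080, 2 exons) went from 62.6 ± 61.6 to 695 ± 134 CPM (SD, n = 3, log2 fold change 2.92 ± 0.56 SE, adjusted p = 0.000269), above every control library in 3 of 3 APAP libraries. The Trpc6 circRNA mmu_circ_0001743 (9:8634047-8658377, 2 exons) went from 15.4 ± 26.7 to 402 ± 55.4 CPM (SD, n = 3, log2 fold change 4.14 ± 1.00 SE, adjusted p = 0.0264), likewise in 3 of 3 libraries. Limma-voom did not pass Epha2 (adjusted p = 0.107) or Trpc6 (adjusted p = 0.226), and DESeq2 passed both. The Trpc6 call ended without control 1 (adjusted p = 0.379), APAP 1 (0.191), APAP 2 (0.292), APAP 3 (0.0928) or dmPGE2+APAP 1 (0.0546). Its log2 fold change was 3.24 without control 1, and control was listed at 0 without control 2, the 1 control library with reads.

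The other calls were uneven within groups. The circRNA novel_circ_0011754 of Erc1, a scaffold protein, was listed at 0 in all control libraries and at 25, 0 and 42 reads after APAP (adjusted p = 0.000269, DESeq2 0.76, and 0.0884 without APAP 3). The circRNA novel_circ_0009634 of the lipid transfer protein gene Scp2 had 51 reads in control 1 and none in the other control or APAP libraries (adjusted p = 0.00535), so this call rested on 1 library. It also ended without APAP 1 (adjusted p = 0.118), APAP 2 (0.116), dmPGE2+APAP 1 (0.179) or dmPGE2+APAP 3 (0.0839). The circRNA mmu_circ_0001283 of Arid1a, a subunit of the SWI/SNF chromatin remodeller, had 9, 0 and 25 reads in control and 0, 15 and 0 after APAP. Its log2 fold change of -3.57 ± 0.79 SE (adjusted p = 0.00535) became 0.56 (adjusted p = 1) without control 3. APAP was listed at 0 without APAP 2, and the call did not pass without APAP 1 (0.232) or APAP 3 (0.149), nor in DESeq2 (0.983) or limma-voom (0.944). Limma-voom did not pass Erc1 (0.665) or Scp2 (0.679) either. Next in order and not passing were circRNAs of Pde5a (novel_circ_0009075, adjusted p = 0.0996), Ercc6 (mmu_circ_0000521, 0.119), Prr5l (novel_circ_0007655, 0.119) and Rsu1 (novel_circ_0007903, 0.133). CPM ranges of the groups lay apart in 379 circRNAs (8.75%). Chance gives 10% only without ties, and libraries tied at 0 lower that level by an amount not computed.

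**Figure D2:**
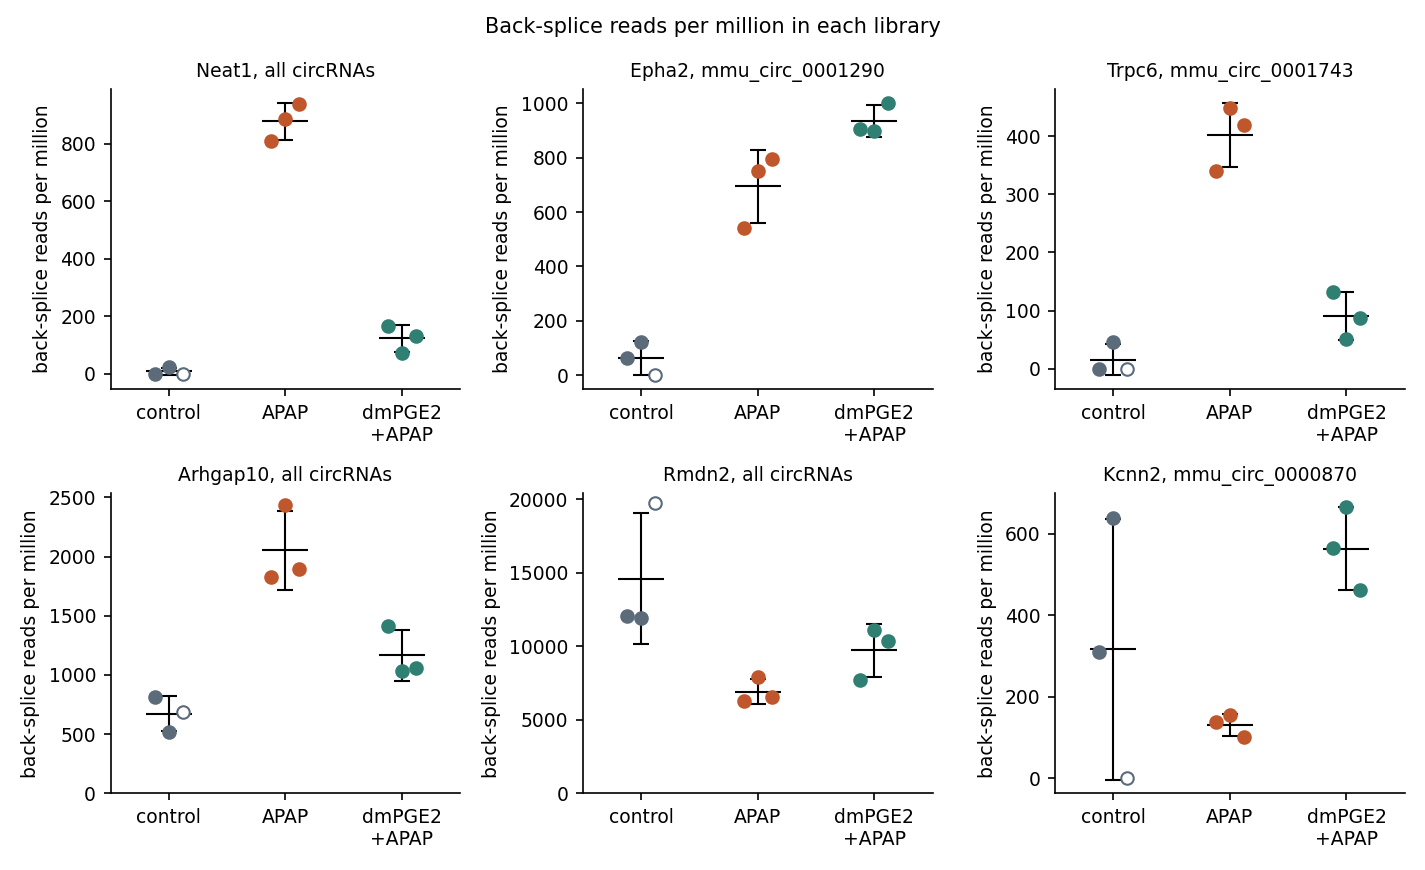
CPM of back-splice reads (vertical axes) per library and group for Neat1 (all its circRNAs), the Epha2 circRNA, the Trpc6 circRNA, Arhgap10 and Rmdn2 (all their circRNAs) and the Kcnn2 circRNA. Points are libraries, the open point is control 3, dashes are means and bars SD (n = 3); Neat1 lies between 810 and 938 CPM in APAP libraries and at 23.1 CPM or less in control.

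Of 2358 host genes, 8 passed, 6 up and 2 down (7 up and 4 down without TMM scaling). Without control 2, control 3 or APAP 3 in turn the count was 5 each time, and the count at an unadjusted p under 0.05 was 126 (117.9 by chance). The latter was 118 by DESeq2 and 186 by limma-voom. Among 1169 host genes with reads in all 8 other libraries, with control 3 left out, it was 104 (58.5 by chance). Neat1 rose 73.6-fold (log2 fold change 6.20 ± 0.90 SE, adjusted p = 1.71e-07) and Epha2 rose with it (2.93 ± 0.55 SE, adjusted p = 0.000356, and 0.0527 without control 1). The Neat1 log2 fold change was 5.25 without control 1, and control was listed at 0 without control 2, the 1 control library with reads. Arhgap10, over 11 circRNAs, went from 671 ± 148 to 2054 ± 335 CPM (SD, n = 3, log2 fold change 1.67 ± 0.36 SE, adjusted p = 0.00326), with 3 of 3 APAP libraries above every control (limma-voom adjusted p = 0.0579, and 0.083 or 0.118 without control 2 or APAP 2). Rmdn2, over 6 circRNAs, went from 14580 ± 4451 to 6909 ± 870 CPM (SD, n = 3, log2 fold change -0.82 ± 0.20 SE, adjusted p = 0.021), with 3 of 3 APAP libraries below every control, and passed in DESeq2 and limma-voom too. Its call ended without control 1 (adjusted p = 0.187), control 2 (0.0708), APAP 1 (0.215), APAP 3 (0.302) or dmPGE2+APAP 3 (0.052). Pde5a, the phosphodiesterase of cyclic GMP, rose 11.3-fold (adjusted p = 0.000706) and the chromatin gene Pwwp2a (adjusted p = 0.00851) and the SUMO protease gene Senp1 (adjusted p = 0.0418) were listed at 0 in every control. Without control 3 these 3 had adjusted p = 0.11, 0.0867 and 0.123, and Arid1a (log2 fold change -4.05 ± 0.94 SE, adjusted p = 0.0101) had 0.61 (adjusted p = 0.999). Without control 2, Pde5a had a log2 fold change of 2.69 in place of 3.50 and an adjusted p of 0.0613. Its control was listed at 0 without control 1, the 1 control library with reads. Limma-voom passed none of these 4 (adjusted p 0.207 to 0.954), and DESeq2 passed Senp1 (0.0337), not Pwwp2a (0.328) or Arid1a (0.987), and gave no adjusted p for Pde5a. Pwwp2a also did not pass without control 1, control 2 or APAP 2 (adjusted p up to 0.971), Senp1 without control 1, control 2, APAP 1, APAP 3, dmPGE2+APAP 2 or dmPGE2+APAP 3 (up to 0.477), and Arid1a without APAP 1 or APAP 3 (0.263 and 0.302).

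Without control 3, and chosen after their values were seen, 3 circRNAs of Rmdn2 with a common start fell (17:79650302, ends 79659473, 79672573 and 79681682; log2 fold changes -0.76, -1.57 and -1.48, adjusted p = 0.0367, 0.00939 and 0.00735). A further circRNA with that start (end 79651801, 0.25) and 1 with another (79666871-79672573, -1.42) did not pass (adjusted p = 1). The circRNA novel_circ_0006604 of Insig2, a protein that retains SREBP precursors in the endoplasmic reticulum, rose in that fit (log2 fold change 1.54 ± 0.34 SE, adjusted p = 0.0224), and mmu_circ_0000870 of Kcnn2, a calcium-activated potassium channel, fell (-1.88 ± 0.44 SE, adjusted p = 0.0367).

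Among the host gene lists, the pericentral hepatocyte genes, which mark cells around the central vein, stood lower after APAP (6 tested host genes, median log2 fold change -1.01, camera adjusted p = 0.0344). This call was lost with adjusted p = 0.997 with an estimated correlation, and it was absent without control 1, control 2, APAP 1 or APAP 3 in turn. None of its 6 host genes passed over all host genes, and 2 passed adjusted over the list alone: Slco1b2, a hepatic uptake transporter (log2 fold change -0.84 ± 0.26 SE, list-alone adjusted p = 0.00851), and the glutamate transporter gene Slc1a2, listed at 0 in all APAP libraries (list-alone adjusted p = 0.0359). Cyp1a2 (-0.34 ± 0.51 SE), Lhpp (-1.67) and Cyp27a1 (-0.22 ± 1.65 SE) did not pass. In drug metabolism, 0 of 16 host genes passed over all host genes and 2 adjusted over the list alone, Slco1b2 (list-alone adjusted p = 0.0227) and Cyp2c70, a bile acid hydroxylase (-0.93 ± 0.32 SE, list-alone adjusted p = 0.0314, adjusted p = 0.914 over all host genes without control 3). The list itself had a camera adjusted p of 0.392. In lipid and bile acid metabolism 1 of 40 passed adjusted over the list alone, Insig2 (1.53 ± 0.43 SE, list-alone adjusted p = 0.0174), and Nr1h4 (-0.19), Scp2 (0.07) and Abca1 (0.08) did not (camera adjusted p = 0.843).

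The other lists had no host gene past the test over all host genes, nor adjusted over the list alone, except 1 fall among 45 widely reported circRNA hosts, Arid1a (camera adjusted p = 0.413, with Nfix at -0.12 and Elf2 at 0.33 not passing). Secreted plasma proteins (24 host genes, adjusted p = 0.509) included Ces1c (-0.63) and Kng2 (-0.45), amino acid and carbohydrate metabolism (35, 0.335) Aass (0.31) and Bckdhb (-0.18), and periportal hepatocytes (14, 0.843) Slc7a2 (0.65) and Cps1 (0.66), in log2 fold change. NRF2 and glutathione (8, 0.994) included Gclc (0.62 ± 0.41 SE), stress response (10, 0.486) Atf6 (0.41) and Ern1 (0.75), inflammation and acute phase (8, 0.486) Crp (-0.53) and Il6st (1.89 ± 0.94 SE), and prostaglandin signalling (10, 0.994) Ptgr2 (-0.19) and Pde4d (2.27 ± 0.96 SE). Sinusoidal endothelial cells (10, 0.335) included Mrc1 (0.09) and F8 (-0.98), splicing and circRNA handling factors (22, 0.994) Ptbp3 (0.25) and Hnrnpu (-0.36), and proliferation (15, 0.994) Cdk8 (0.88) and Stag1 (0.34). Kupffer cells and macrophages (3 host genes, Adgre1 at -0.12), neutrophils and lymphocytes (1, Ets1 at 0.41), stellate cells and fibroblasts (4, Fn1 at -0.32) and cholangiocytes (2, Pkhd1 at 0.83) had too few host genes for camera and none passed. Over the 17 lists other than the widely reported circRNA hosts, 0 of 208 host genes passed in edgeR, DESeq2 passed 2 (Insig2 and Slco1b2) and limma-voom 0. In edgeR 21 of the 208 had an unadjusted p under 0.05, a larger share than the 126 of all 2358 host genes. Whether this excess goes beyond chance was not tested. The median and the camera direction differed in sign for secreted plasma proteins, periportal hepatocytes, prostaglandin signalling, splicing factors and proliferation, and median and mean for periportal hepatocytes.

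The comparison of dmPGE2+APAP with APAP asked which circRNAs differ when the prostaglandin analogue is given 1 hour before the overdose. Neat1 back-splice reads were 6.91-fold lower with dmPGE2, at 122 ± 48.2 CPM against 878 ± 64.7 CPM (SD, n = 3), in 3 of 3 libraries. All 3 lay above every control library, but against control the Neat1 sum did not pass (adjusted p = 0.146). No single Neat1 circRNA passed with dmPGE2 against APAP. The circRNA novel_circ_0006472 stood at 460 ± 118 CPM after APAP and 114 ± 38.0 CPM with dmPGE2 (SD, n = 3). Every other Neat1 ring read after APAP had at most 20 reads per library there and was listed at 0 with dmPGE2, which need not mean that no read was seen. Summed over its circRNAs, the zinc finger gene Zfp609 fell 9.32-fold, and the kinase gene Hipk3 was listed at 0 in all dmPGE2+APAP libraries, with 208, 0 and 0 reads after APAP. The Kcnn2 circRNA stood at 132 ± 27.7 CPM after APAP and 564 ± 102 CPM with dmPGE2 (SD, n = 3), but did not pass with all libraries.

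By edgeR, 3 of 4331 circRNAs passed, 1 up and 2 down, 0 by DESeq2 and 0 by limma-voom, with 162 at an unadjusted p under 0.05 in edgeR, 159 in DESeq2 and 288 in limma-voom (216.6 by chance). Without dmPGE2+APAP 3 the count was 1. The intronic novel_circ_0001607 of Akap1 (11:88849426-88850194), which anchors protein kinase A to mitochondria, had 128, 117 and 124 reads after APAP and 104, 0 and 0 with dmPGE2 (log2 fold change -2.07 ± 0.45 SE, adjusted p = 0.00557, and 1 without control 3, dmPGE2+APAP 2 or dmPGE2+APAP 3). It also did not pass without APAP 1 (0.0682) or APAP 3 (0.254), and its log2 fold change was -1.49 and -1.48 without dmPGE2+APAP 2 and 3, and the group was listed at 0 without dmPGE2+APAP 1, its 1 library with reads (limma-voom adjusted p = 0.149 with all libraries). The Zfp609 circRNA mmu_circ_0001797 (9:65794622-65795495) had 171, 160 and 0 reads after APAP and was listed at 0 in the 3 dmPGE2+APAP libraries (adjusted p = 1.82e-23, DESeq2 0.787). The Scp2 circRNA novel_circ_0009634 was listed at 0 after APAP and at 55, 0 and 52 with dmPGE2 (adjusted p = 0.000125, limma-voom 0.442, and 0.0775 or 0.0626 without dmPGE2+APAP 1 or 3). Each of these 3 circRNAs was at 0 in some libraries of a group whose other libraries held over 50 reads. The Kcnn2 circRNA mmu_circ_0000870 (18:45592006-45592424, 1 exon) had log2 fold change 2.11 ± 0.57 SE (adjusted p = 0.205, and 0.00948 without control 3), higher in 3 of 3 libraries. Also not passing were circRNAs of Fbxo31 (novel_circ_0013451, adjusted p = 0.753), Smarca2 (novel_circ_0006045, 0.905), Wwp2 (novel_circ_0013370), Nr1h4 (novel_circ_0000600), Prdx6 (novel_circ_0006904) and Lima1 (novel_circ_0004240), the last 4 with adjusted p = 1. CPM ranges lay apart in 397 circRNAs (9.17%), where chance gives 10% only without ties at 0.

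Of 2358 host genes, 3 fell and none rose, with 64 at an unadjusted p under 0.05 (117.9 by chance), 1 passing in DESeq2 and 0 in limma-voom. Neat1 had log2 fold change -2.79 ± 0.62 SE (adjusted p = 0.00805, DESeq2 4.39e-05, limma-voom 0.06). This call ended without APAP 1 (adjusted p = 0.115), APAP 2 (0.203), APAP 3 (0.107), dmPGE2+APAP 2 (0.264) or dmPGE2+APAP 3 (0.0923), with log2 fold changes of -2.84 to -2.51. Zfp609 had -3.22 ± 0.48 SE (adjusted p = 2.52e-07, DESeq2 0.79). Hipk3 had an adjusted p of 2.01e-08 (limma-voom 0.923), and its call rested on APAP 1. The count was 1 without APAP 1, 5 without control 2, 6 without dmPGE2+APAP 1 and 5 with the replicate number as a block. No list passed in camera (adjusted p 0.151 to 0.815, 1 of 14 lists at an unadjusted p under 0.05), and neither did any with an estimated correlation or in fry. The pericentral list had a median log2 fold change of 1.10 (adjusted p = 0.151), with Lhpp at 2.53 and Slco1b2 at 0.42 ± 0.25 SE not passing. That list passed without APAP 2 (adjusted p = 0.0414) and without dmPGE2+APAP 2 (0.0192). Median and mean differed in sign for prostaglandin signalling, proliferation, and stellate cells and fibroblasts, and median and camera direction for prostaglandin signalling and proliferation. Zfp609 and Hipk3 belong to the widely reported circRNA hosts, of which 0 rose, 2 fell and 43 did not pass (2 adjusted over the list alone, camera adjusted p = 0.595). Over the other 17 lists 0 of 208 host genes passed in edgeR, DESeq2 or limma-voom, 5 with an unadjusted p under 0.05, among them no call for Ptgr2 (-0.05), Gclc (-0.21) or Nfkb1 (0.24).

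**Figure D3:**
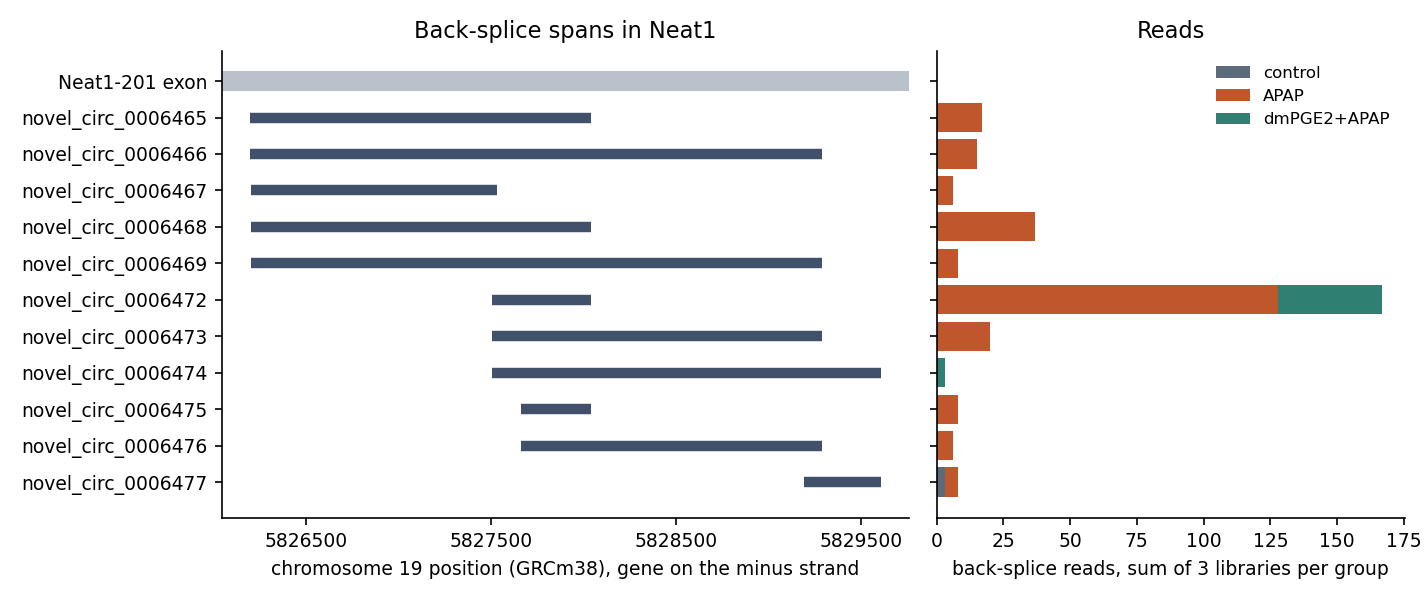
Positions of the 11 Neat1 circRNAs on chromosome 19 (left, bases of GRCm38) and their back-splice reads per group, summed over 3 libraries (right, stacked reads per circRNA). The rings lie between 5826197 and 5829611, and novel_circ_0006472 makes up the largest part of the reads after APAP and with dmPGE2.

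The comparison of dmPGE2+APAP with control asked which circRNAs differ from saline when both compounds were given. The Epha2 circRNA rose 10.7-fold, to 935 ± 58.2 CPM from 62.6 ± 61.6 CPM (SD, n = 3), in 3 of 3 libraries. The Neat1 circRNA novel_circ_0006472 rose to 114 ± 38.0 CPM (SD, n = 3) from a control listed at 0. Zfp609 fell 9.69-fold over its host sum.

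By edgeR, 5 of 4331 circRNAs passed, 3 up and 2 down (10 without TMM scaling, 4 up and 6 down), with 188 at an unadjusted p under 0.05. The count was 8 without control 1 and 8 without dmPGE2+APAP 2, and 3 with the replicate number as a block. Epha2 mmu_circ_0001290 had log2 fold change 3.42 ± 0.56 SE (adjusted p = 2.26e-06, limma-voom 0.017) and Neat1 novel_circ_0006472 an adjusted p of 0.00932 (DESeq2 0.113, limma-voom 0.483), a call that ended without control 1, control 2, APAP 2 or dmPGE2+APAP 1 (up to adjusted p = 1 over its alternatives). Zfp609 mmu_circ_0001797 was listed at 0 with dmPGE2 and at 207, 155 and 0 in control (adjusted p = 6.81e-23, DESeq2 0.68), and Erc1 novel_circ_0011754 at 0 in control and 0, 43 and 47 with dmPGE2 (adjusted p = 0.00013, DESeq2 1, limma-voom 0.661). Arid1a mmu_circ_0001283 had -4.13 ± 0.81 SE (adjusted p = 0.000366, DESeq2 1, limma-voom 0.976), 0.04 (adjusted p = 1) without control 3, and -4.96 to -3.56 without any other single library. Next and not passing were circRNAs of Zfp644 (mmu_circ_0001382, adjusted p = 0.0704), Klc2 (novel_circ_0006407, 0.14), Ercc6 (mmu_circ_0000521, 0.169) and Abcc6 (novel_circ_0013048, 0.333), and the intergenic novel_circ_0010359 (4:60069733-60138460, -1.07 ± 0.32 SE, 0.333). CPM ranges lay apart in 426 circRNAs (9.84%), where chance gives 10% only without ties at 0.

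Of 2358 host genes, Epha2 rose (log2 fold change 3.38 ± 0.56 SE, adjusted p = 3.88e-06) and Zfp609 (-3.28 ± 0.49 SE, adjusted p = 1.96e-07), Hipk3 (listed at 0 with dmPGE2 and at 5, 195 and 0 in control, adjusted p = 3.9e-08) and Arid1a (-4.63 ± 0.97 SE, adjusted p = 0.00197) fell. DESeq2 and limma-voom passed Epha2 alone: Zfp609 had 0.732 and 0.414 and Arid1a 1 and 0.999, and Hipk3 had 0.732 in limma-voom and no adjusted p in DESeq2. The Arid1a log2 fold change was 0.05 without control 3, Hipk3 rested mainly on control 2 (adjusted p = 0.65 without it), and the count of 4 was 8 without control 1. These 3 falls were the 3 of 45 widely reported circRNA hosts that passed, over all host genes and adjusted over the list alone. No list passed in camera (adjusted p 0.688 to 0.859), with an estimated correlation or in fry, and 0 had an unadjusted p under 0.05 in camera. Over the other 17 lists 0 of 208 host genes passed in edgeR, DESeq2 or limma-voom. At an unadjusted p under 0.05 in edgeR there were 11, against 100 of all 2358 host genes. Medians were -0.14 for pericentral hepatocytes, -0.03 for drug metabolism and 0.32 for prostaglandin signalling, in log2 fold change. Median and camera direction differed in sign for secreted plasma proteins, sinusoidal endothelial cells and splicing factors, and median and mean for drug metabolism, amino acid and carbohydrate metabolism, widely reported circRNA hosts and splicing factors.

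The joint test of the 3 groups passed 9 circRNAs, those of Akap1, Scp2, Epha2, Trpc6, Neat1, Zfp609, Erc1 and Arid1a named above and, not passing in any pair, novel_circ_0013451 of Fbxo31 (listed at 0 in control and APAP and at 5, 12 and 53 reads with dmPGE2, adjusted p = 0.0344). It passed 8 host genes. Without dmPGE2+APAP 3 the count of circRNAs was 5.

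The last question was whether changes with dmPGE2 ran against those of APAP. Across 4331 circRNAs, which are not independent replicates, the log2 fold changes of dmPGE2+APAP with APAP and of APAP with control had a Pearson correlation of -0.515 and a covariance of -1.74. The shared APAP libraries alone gave -0.485 (-0.512 to -0.444 in 30 simulations) and a covariance of -1.80 (-1.95 to -1.54). The correlation thus lay just below every simulation, and the covariance within their range. The correlation also lay below its own simulated range with at least 10 reads (-0.549), without TMM scaling (-0.51) and without control 3 (-0.504), and above it without control 1 (-0.386 against -0.437 to -0.388), with the covariance within its range each time. Without APAP 1 or APAP 2 both lay beyond the simulations, at correlations of -0.695 and -0.672 and covariances of -3.80 and -3.39, against simulated covariances no lower than -2.85 and -2.90. Against control, the changes of both treated groups correlated at 0.613 (covariance 2.25), where shared controls alone gave 0.538 (0.513 to 0.583) and a covariance of 2.07 (1.91 to 2.23), so that both lay above every simulation. Without control 1 the correlation was 0.786 (0.655 to 0.68 simulated) and the covariance 5.11 against at most 3.56, and without control 2 the covariance was 4.12 against at most 3.49. Without control 3, APAP 1 or dmPGE2+APAP 1 the covariance was 2.64, 2.09 or 2.17, within its simulated range, though without control 3 the correlation of 0.641 lay above its own (0.57 to 0.613). With reads in all 8 other libraries and control 3 left out, both lay above the simulations (0.643 against at most 0.615, and 0.229 against at most 0.196).

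Of the calls, 1 circRNA (Scp2) was called in opposite directions in APAP with control and dmPGE2+APAP with APAP, where independent lists of that size give 0.00231. Simulations without any effect, taking lists as long as the real ones by smallest p, gave a mean of 0.7 such circRNAs, and the Scp2 call against control rested on control 1. Neat1 was the 1 such host gene (0.00763 for independent lists, a mean of 0.5 simulated). Without control 3, 2 circRNAs were called in opposite directions (a mean of 0.767 and at most 3 in the simulations) and 1 host gene (0.733 and at most 2). In the same direction against control, 4 circRNAs were shared (Epha2, Neat1, Erc1 and Arid1a, 0.00369 for independent lists, a mean of 0.9 and at most 2 in the simulations) and 2 host genes (Epha2 and Arid1a, 0.00509 for independent lists, a mean of 1 and at most 3 in the simulations). Without control 3 these were 3 circRNAs, where simulations reached 3, and 1 host gene, where they reached 2. Part of either excess over independent lists may come from the shared libraries, which the simulations hold. Against simulated lists of the real length, the overlaps in opposite directions showed no excess. By the threshold itself, with all libraries, 5 of 30 simulations shared such a circRNA and 0 of 30 such a host gene. Those simulations called fewer host genes (means of 0.167 and 0.133, against 8 and 3), so few could be shared and this count decides nothing. Of the circRNAs shared in the same direction, Arid1a turned without control 3. Erc1 had zeros in single libraries of the kind described below, which were not built into the simulations.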

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

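The fits limited to features with reads in all 8 libraries other than control 3, the fit of list correlations without that library and all splits of the libraries were chosen after the results were seen; the other alternatives were planned. Among circRNAs named in the report, Neat1 novel_circ_0006472 in APAP with control (adjusted p 1.02e-06 to 0.0202) and Epha2 in dmPGE2+APAP with control (1.01e-11 to 0.017) stayed past the threshold in the same direction under every alternative that tested them; the Neat1 circRNA, at 0 in control, was not in the fits limited to reads in all 8 libraries. Of 53 named values 14 were past the threshold, and 12 of these were lost under at least 1 alternative. Of the 39 others, 19 changed sign and 9 passed under some alternative. Over libraries left out in turn, the Arid1a circRNA mmu_circ_0001283 had log2 fold changes of -8.89 to 0.562 in APAP with control and -4.956 to 0.038 in dmPGE2+APAP with control, turning without control 3. The value of -8.89 is against APAP libraries all at 0, so it depends on the prior count and is no bound. The Scp2 circRNA novel_circ_0009634 had -7.522 to 0 in APAP with control, with 0 without control 1, where all remaining libraries were at 0; all of these are against APAP libraries at 0 and likewise no bound. Without TMM scaling the median log2 fold change of all circRNAs in dmPGE2+APAP with control was 0.13 in place of 0.25. Without control 3 it was 0.004, and in APAP with control -0.063 in place of 0.165. Where no cause is given, the cause was not tested.

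Counts follow for APAP with control (6 circRNAs, 8 host genes), dmPGE2+APAP with APAP (3 and 3), dmPGE2+APAP with control (5 and 4) and the joint test (9 and 8), where they moved by over 1.5 times. DESeq2 gave 14, 0 and 1 circRNAs and 13, 1 and 1 host genes in the 3 comparisons. Limma-voom gave 0 and 2 circRNAs in the comparisons that hold dmPGE2+APAP, 2, 0 and 1 host genes in the 3 comparisons and 3 host genes jointly. Without TMM scaling there were 12 and 10 circRNAs against control and 13 host genes jointly. With no filter on low counts there were 9 and 12 circRNAs in the comparisons that hold dmPGE2+APAP and 19 jointly, and 6 host genes in dmPGE2+APAP with APAP (6 too with at least 2 reads) and 13 jointly. With at least 10 reads, where fewer features were tested, there were 2, 1 and 3 circRNAs and 3 jointly, and 4 and 2 host genes against control and 4 jointly. Reads in all 8 other libraries, which removed features at 0 in any of them, left 1, 0 and 1 circRNAs and 1 jointly, and 3, 1 and 2 host genes and 4 jointly. With control 3 also left out there were 1 and 1 circRNAs and 5 and 2 host genes in the comparisons that hold dmPGE2+APAP.

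Leaving out 1 library at a time gave 3 to 10, 1 to 3 and 4 to 8 circRNAs in the 3 comparisons and 5 to 10 jointly. For host genes it gave 5 to 8, 1 to 6 and 3 to 8, and 6 to 11 jointly. The lists past camera ranged from 0 to 1 in APAP with control and from 0 to 1 in dmPGE2+APAP with APAP. The p for exonic shares ranged from 0.03214 to 0.08571 and was 0.1071 on the percent of circRNAs, and that for intergenic shares ranged from 0.03571 to 0.1536. The correlation of dmPGE2+APAP with APAP against APAP with control ranged from -0.695 to -0.386, and that of both treated groups against control from 0.469 to 0.786, in each case with its own simulated range. The pericentral list called in APAP with control gave 0 lists with an estimated correlation, 0 with fry, 0 without TMM scaling, 0 with reads in all 8 other libraries and control 3 left out, where it had too few host genes, and 0 with an estimated correlation and control 3 left out.

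The replicate numbers did not pair the libraries, since deviations of libraries with the same number correlated at 0.04 at most. With the replicate block there were 4, 3 and 3 circRNAs and 7 jointly, 6, 5 and 3 host genes and 7 jointly, and 0, 0 and 0 lists. The replicate block moved by over 1.5 times only the 3 circRNAs in dmPGE2+APAP with control, the 5 host genes in dmPGE2+APAP with APAP and the 0 lists in APAP with control. Scaling the totals by another deposited library size was not run, since the deposited constants lie close to the circRNA totals, which make up 99.53% to 99.95% of them. In simulations with these depths, this spread and 3 libraries per group, 1.49% of 2-fold and 36.1% of 8-fold changes of circRNAs were recovered for APAP with control, and depth alone was not varied.

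With 10 splits of 6 libraries no share under 0.05 can be reached. The real split gave 6 circRNAs in APAP with control (1 of 10 splits as many, highest other 4), 3 in dmPGE2+APAP with APAP (6 of 10, highest other 3) and 5 in dmPGE2+APAP with control (6 of 10, highest other 7). For host genes these were 8 (1 of 10, highest other 3), 3 (3 of 10, highest other 3) and 4 (6 of 10, highest other 6), and for lists 1 (2 of 10, highest other 1), 0 (10 of 10, highest other 1) and 0 (10 of 10, highest other 0). In 100 splits of all libraries into 3 groups, 9 gave at least the 9 circRNAs of the joint test (highest other 12) and 5 at least its 8 host genes (highest other 9), so chance cannot be excluded for either count.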

Other observations

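All tests in this part were chosen after the results were seen. Host genes with reads in all 8 libraries other than control 3, tested without that library, gave 9 of 1169 past the threshold in APAP with control and 5 in dmPGE2+APAP with APAP. After APAP, host sums of Acsm1, a medium-chain acyl-CoA synthetase gene, of the glycosyltransferase-domain gene Glt1d1 and of the uptake transporter gene Slco1b2 fell in that fit and that of Rsu1, a regulator of cell adhesion, rose, besides Rmdn2, Epha2, Arhgap10, Insig2 and Kcnn2. Under the planned filter without control 3, adjusted p was 0.116 for Acsm1, 0.271 for Glt1d1, 0.0862 for Slco1b2, 0.215 for Rsu1 and 0.113 for Kcnn2. None of these passed with all libraries, where Glt1d1 had a log2 fold change of -0.245. With dmPGE2 against APAP, Rmdn2 (log2 fold change 0.49 ± 0.12 SE, adjusted p = 0.015), Kcnn2 and Upp2, a uridine phosphorylase gene of liver (0.73 ± 0.19 SE, adjusted p = 0.0291), rose, and Spopl and Zfp609 fell. Of these, Zfp609 alone passed with all libraries too. Rmdn2 (adjusted p = 0.108), Spopl (0.492) and Upp2 did not pass without control 3 under the planned filter either. Spopl was uneven, with 2, 126 and 54 reads after APAP and 16, 15 and 17 with dmPGE2. Single circRNAs of Ehbp1 (mmu_circ_0000245, 0.96 ± 0.24 SE, adjusted p = 0.0194) and Bckdhb (novel_circ_0014841, -0.77 ± 0.20 SE, adjusted p = 0.0347) also passed in APAP with control.

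Circular and linear forms were compared at 1125 circRNAs with usable non-junction reads in those 8 libraries. Across them, which are not independent replicates, log2 changes of circular and non-junction reads had Pearson 0.137, 0.0703 and 0.106 and Spearman 0.141, 0.0839 and 0.102 in APAP with control, dmPGE2+APAP with APAP and dmPGE2+APAP with control. The circular share was 66.9% ± 0.809 in control (SD, n = 2), 60.0% ± 4.77 in APAP and 62.3% ± 1.03 in dmPGE2+APAP (SD, n = 3, exact permutation p = 0.143 over 560 arrangements). At the 391 circRNAs of all 9 libraries the exact permutation p was 0.989. Among 883 pairs of circRNAs from the same host (288 hosts), changes correlated at 0.122 (permutation p = 0.002), 0.0816 (0.011) and 0.0285 (0.17) in the 3 comparisons, with 1000 permutations each. Host labels were permuted over circRNAs with the libraries held fixed. These p-values therefore do not measure the spread between samples and do not tie the agreement to treatment.

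Control 3 had few back-splice reads. Shallow sequencing is argued against, since its non-junction reads at the same 391 circRNAs were 2.698 times the median of the other 8 libraries (70529 against 22938 to 29750). Another tissue is argued against too: 6 hepatocyte lists joined (5 host genes, 6 circRNAs) held 14.53% of its non-junction reads (95% Wilson interval 14.3% to 14.8%) against 1.992% to 3.787%, most of it from 2 circRNA sites of Cyp2c70 with 7787 reads against 142 to 592. Linear RNA retained in control 3 alone may account for the pattern, as the lists without Cyp2c70 held 3.491% (3.36% to 3.63%) against 1.373% to 1.731%, but these are 4 host genes. The library also differed in which circRNAs it held: thinned to 4362 reads, its Spearman correlation with the rest was 0.481 against 0.667 to 0.728, and its non-junction reads correlated at 0.426 to 0.509 with the other libraries, against 0.718 to 0.886 among those, a value another tissue would also give, so a mislabelled library or one made in another way stays open, and the treatments give no biological explanation to test, because control 1 and 2 share its group.

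Some abundant circRNAs were all or none: of 604 expected to hold at least 20 reads per library, 17 were at 0 in at least 1 of the 8 other libraries, 37 of 4832 values in all, among them the called circRNAs of Zfp609, Erc1 and Akap1. Sampling noise is argued against, since a negative binomial wide enough for these zeros (BCV 2.01) gives 43.9 ± 5.42 (SD) values above 0 and at most at 0.25 of the expected count among the 136 values of the 17, where 0 were seen. That model takes no account of the choice of members by high counts where read. It also counts values of 1, which the data never hold, so 43.9 may be too high by an amount not computed. For these 17 as a set, the treatment group alone is argued against as well: all 17 had zeros and reads within 1 group, and 182 of 280 splits of the 8 libraries gave as many groups uniformly at 0 or above it (22 real, highest other 32). Members needed reads in at least 4 of the 8 libraries, so a circRNA read in 1 group alone could not enter. Of the 17, 1 was at 0 in every control library of the 8 and 1 in every dmPGE2+APAP library, and for single members the test decides nothing. Another member was mmu_circ_0001165 of Pde5a, whose 26, 0 and 0 reads in control were all the control reads of that host gene. The host gene call of Pde5a in APAP with control may thus rest partly on such zeros. A junction dropped at the calling step of single libraries stays open: over all 604, 6 values lay in that low range against 37 at 0, but this is how the pattern was seen and decides nothing. Of the 17, 13 had at most 1 exon against 76 of the 587 others (Fisher's exact p = 1e-08), and the caller's rules stay unknown here.

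The table held 11 Neat1 rings, 10 of them with reads after APAP, within 19:5826197-5829611, inside a transcript annotated as 1 exon (19:5824708-5845478), and 0 had both ends at annotated exon ends. The deposited features list up to 3 exons for a ring. They give novel_circ_0006472 a spliced length of 289 bases, shorter than its span, so spliced forms are annotated there as well. Template switching at repeats is argued against, since the longest direct repeat across any of the 11 junctions was 2 bases, where at least 5 were looked for. More linear Neat1 RNA cannot be told apart from more back-splicing, since 0 of the circRNAs had non-junction values in both control and APAP libraries. The APAP treatment stays open as untested, since the gap between the lowest APAP library (809.81 CPM) and the highest control (23.08 CPM) is the pattern itself. All 11 junctions were flanked by AG and GT, which a caller that keeps only such junctions would also give.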
